A study of Mus musculus with 24 samples.

How the data were processed

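PolyA RNA sequencing (TruSeq stranded mRNA) of 24 mouse embryonic stem cell libraries, from 4 genotypes on 2 days with 3 libraries in each of 8 groups, was analysed as 1 deposited table of normalized counts for 19953 genes. Its unit is recorded here as signal, and the deposited signal was the gene read count of a library divided by 1 size factor for that library. Multiplied by its size factor, 100% of values were whole at a tolerance of 1e-06, so whole read counts were recovered for the count models. No gene was 0 in every library, and no column of values was left without a sample. The names of the day 0 WT columns carry an added letter that the labels do not explain, and they were taken as day 0 WT because they were the only WT columns of that day. Per the submitters' processing notes the tools were FastQC, Trim Galore 3.4, STAR 2.7.10a, RSEM 1.3.1, SAMtools 1.13 and DESeq2 1.34.0 with the mm10 build, and the gene annotation was not given in the sources used here. How RSEM assigned reads from near-identical copies was not stated either, so the recovered whole counts may be rounded estimates rather than plain read counts. Recovered totals ran from 10.7 to 22.8 M reads per library, lower at day 4 than at day 0, and 15758 to 16970 genes per library were above 0. Positions were taken from GENCODE mouse release 21, in which 97.3% of the symbols (19405) were found, and symbols with several loci were given none.

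Groups were set by genotype and day. Within each day every mutant was compared with WT, the double-KO with each single mutant, and the difference of Mll2 effects with and without MLL1 was tested as non-additivity. Across days WT was compared at day 4 against day 0, and the change of each mutant effect between days was tested as an interaction. Overlaps of called genes were taken between pairs of comparisons that share no library, with the number expected from the margins. The groups, comparisons, tests and most alternatives were fixed before the data were examined, and alternatives leaving the day 0 WT libraries out of the fit were added afterwards. Replicate numbers carried no pairing: residuals of libraries of the same number in different groups correlated with a median r of 0.0175, so the main test used no block.

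The main test was limma 3.58.1 in R 4.3.3, with a trend, on log2 of the normalized count plus 1. Genes with at least 10 in at least 3 libraries were kept, and the fit held the libraries of 1 day, or all 24 for comparisons across days. This left 13984 genes at day 0, 14303 at day 4 and 15114 across days. A gene was called at a Benjamini-Hochberg adjusted p below 0.05. Gene lists fixed in advance were tested with camera at a preset correlation of 0.01 and again with an estimated correlation, for lists with at least 5 measured members, and list members were also adjusted over the list alone. The lists covered COMPASS family, Hox, naive and formative pluripotency, 2-cell-like, germline, primordial germ cell, endoderm, mesoderm, neural, neural crest, trophectoderm, fibroblast, imprinted, protocadherin, retinoic acid, p53, stress response, cholesterol, interferon, DNA methylation, Polycomb, glycolysis and hypoxia genes, genes reported earlier to depend on MLL2, and mitochondrial and Y chromosome genes. Alternatives were pseudocounts of 0.5 and 5, no filter, a minimum of 50, quantile scaling, scaling to column totals, a replicate block, other libraries in the fit, edgeR 4.0.16 quasi-likelihood with TMM, DESeq2 1.42.0, and leaving out each library in turn.

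Genes were named by rule: Kmt2a and Kmt2b, and in each comparison of 2 groups the 10 largest rises and 10 largest falls among called genes with a mean of at least 50 in the higher group and no overlap of the 3 and 3 libraries, a condition that 10% of random splits meet. Unnamed gene models were passed over. From each list up to 2 rises and 2 falls were named, and for non-additivity and interactions 5 in each direction without the overlap condition. Magohb was added as a gene reported earlier to depend on MLL2. Where 1 group had no reads the fold was given as a lower bound from a floor of 3 counts per library, and where it had 1 to 3 reads in all as a ratio with a 95% counting interval.

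The pipeline was tested on simulated counts, drawn at the WT means with the dispersions and size factors of the real libraries. Known changes, as many rises as falls, were put into a small set of genes in the Mll2-KO group alone. At day 0 limma called 185 genes in the simulation against 6596 in the real comparison. The rates below therefore do not carry over to such broad changes or to genes with few reads, and scaling was not tested. limma recovered 76.1%, 94% and 98.5% of changes of 1.5, 2 and 4 times in the day 0 design, with 3.2% false calls, and 80.6%, 92.5% and 100% at day 4, with 5.7% false calls. False calls were 2.7% and 7.5% for edgeR and 7.7% and 4.3% for DESeq2. Between replicates the chi-square per degree of freedom was 1.852 to 11.48, above the value of 1 for counting error alone. The highest values, 11.48 and 11.43, were of replicate 3 of the day 0 Mll2-KO against replicates 1 and 2, which gave 3.538 between them. Leaving replicate 3 out gave 1462 calls of day 0 non-additivity against 1277, and 5784 against 6596 for Mll2-KO against WT at day 0. LINE1 elements and chromatin data were not analysed here, because the table holds genes only. Mitochondrial genes were absent from this table and Y chromosome genes had too few reads to be tested.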

Results

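Gene expression was measured by polyA RNA sequencing in mouse embryonic stem cells of 4 genotypes on 2 days, with 3 libraries in each of the 8 groups and 24 libraries in all. The genotypes were wild type (WT), Mll1-KO, a Cre-inducible Mll2-KO, and the double-KO. Day 0 cells were kept on gelatin with LIF and 15% serum, and day 4 cells were differentiated with 1 µM retinoic acid in 10% FBS without LIF. Mll2-KO and double-KO cells had been treated with 800 nM 4-OHT for 48 h, whereas WT and Mll1-KO cells were untreated, so loss of Mll2 and the drug could not be separated in any comparison. The labels do not say whether the 3 replicates of a group were separate cultures, so each p-value measured the spread between these samples. Read totals recovered from the table ran from 17.7 to 22.8 M (mega) at day 0 and from 10.7 to 17.1 M at day 4. Levels below are normalized counts, as mean ± SD with n = 3 libraries per group, and changes are log2 fold changes with adjusted p-values from limma. Intervals and lower bounds given for genes with almost no reads in 1 group cover counting error only, and the reads carried no molecular identifiers. Positions are on mm10.

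The targeted genes were read first, to see whether the Mll1 deletion was visible in the reads. Kmt2a, which encodes MLL1 (chromosome 9, 44803355 to 44881296), fell at day 0 from 1090 ± 37.8 in WT to 29.7 ± 11.8 in Mll1-KO (log2 -5.22, 37.2-fold lower, adjusted p = 4.7e-14) and to 29.7 ± 8.36 in the double-KO (-5.19, adjusted p = 3.3e-14). At day 4 it fell from 2140 ± 106 to 55.9 ± 13.7 in Mll1-KO (-5.26, 38.3-fold lower, adjusted p = 4.5e-20) and to 104 ± 24 in the double-KO (-4.37, 20.7-fold lower). The day 4 double-KO held more Kmt2a reads than the day 4 Mll1-KO (0.89, adjusted p = 2.6e-06). In Mll2-KO, Kmt2a was 1380 ± 87 at day 0 (0.34, adjusted p = 0.17) and 2360 ± 71.7 at day 4 (0.14, adjusted p = 0.39). These p-values used a spread shared with the low counts of the Mll1-null groups, so they do not show that Kmt2a was unchanged. The Mll2-KO libraries lay above those of WT at day 0 (1300 to 1473 against 1047 to 1121) and day 4 (2292 to 2436 against 2029 to 2239). Kmt2b, which encodes MLL2 (chromosome 7, 30568858 to 30588726), was 2850 ± 48.2 in WT, 3380 ± 292 in Mll1-KO (0.24, adjusted p = 0.0047), 2540 ± 226 in Mll2-KO (-0.17, adjusted p = 0.033) and 2640 ± 137 in the double-KO (-0.11, adjusted p = 0.14) at day 0. At day 4 Kmt2b was 2270 ± 57.4 in WT and 2500 ± 189 in Mll2-KO (0.14, adjusted p = 0.037). A count over the whole Kmt2b gene cannot tell whether single exons were removed, so these values checked nothing on the Mll2 deletion. Magohb, a gene of the exon junction complex described before as depending on MLL2 (chromosome 6, 131284388 to 131293244), fell at day 0 from 191 ± 13.8 in WT to 40.9 ± 7.71 in Mll2-KO (-2.21, 4.64-fold lower, adjusted p = 2.6e-09) and to 29.5 ± 3.71 in the double-KO (-2.66). At day 4 Magohb fell from 93.1 ± 15.4 to 3.44 ± 1.57 in Mll2-KO (-4.45, 21.9-fold lower, adjusted p = 2.6e-11) and to 3.29 ± 1.18 in the double-KO (-4.48), while Mll1-KO held 230 ± 16 at day 0 and 90.9 ± 9.52 at day 4.

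**Figure D1:**
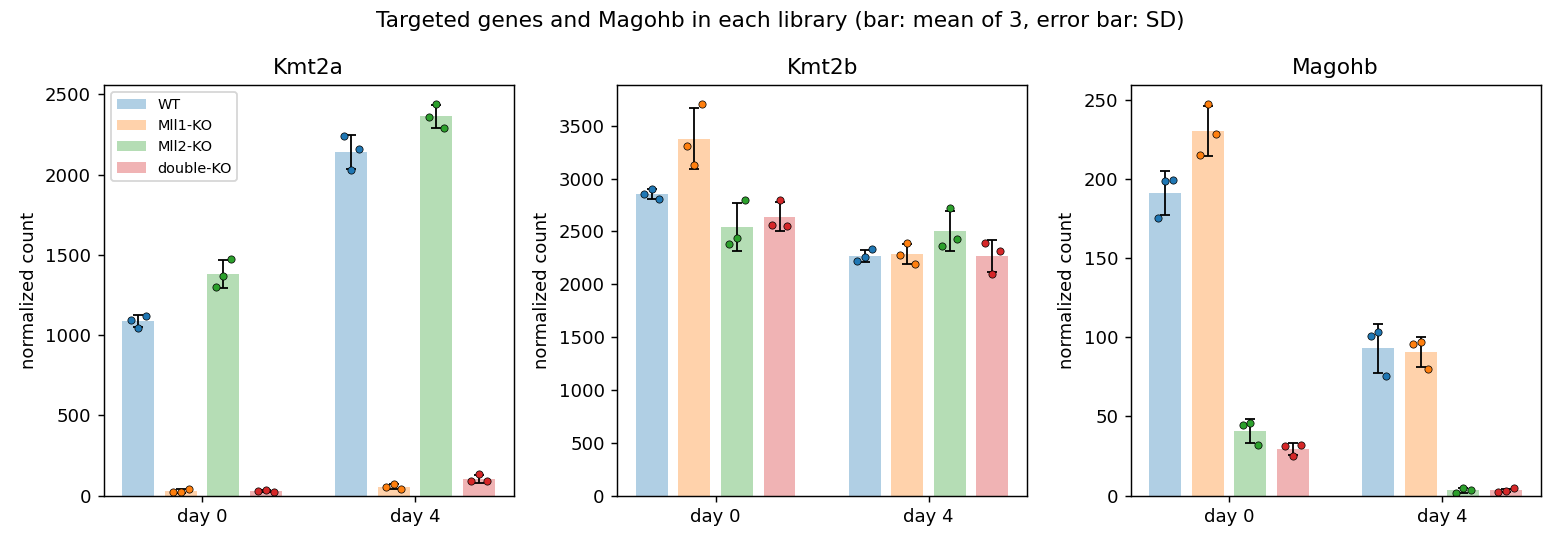
Normalized counts per library of Kmt2a, Kmt2b and Magohb in the 4 genotypes at day 0 and day 4. Points are libraries, bars are means of 3 libraries and error bars are SD.

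The comparison of Mll1-KO with WT at day 0 asked what loss of MLL1 changed in stem cell culture without drug. Several endoderm genes were among the largest falls: Srgn (chromosome 10, 62493833 to 62527451), a proteoglycan core protein, fell from 696 ± 39.8 to 38.7 ± 7.06 (-4.15, adjusted p = 5.1e-13), and Dab2 (chromosome 15, 6299788 to 6440712), an endocytic adaptor of the visceral endoderm, fell from 1530 ± 173 to 112 ± 7.55 (-3.76, adjusted p = 2.1e-15). Hnf4a (chromosome 2, 163506808 to 163572910), a transcription factor of liver and visceral endoderm, fell from 63.2 ± 10.2 to 3 ± 2.63 (-4.36, adjusted p = 7.4e-07). Wt1 (chromosome 2, 105126529 to 105173616) rose from 59.3 ± 6.35 to 222 ± 16.5 (1.89, adjusted p = 1.3e-07), the neuronal intermediate filament gene Ina (chromosome 19, 47014698 to 47025327) rose from 456 ± 23.2 to 1590 ± 111 (1.80, adjusted p = 1.7e-13), and Myc rose from 427 ± 79.1 to 1270 ± 70.4 (1.58, adjusted p = 1.4e-09). Other large falls were in Xlr3a (-4.63), which has near-identical copies, and in Aqp8 (-4.15), A2m (-4.01), Nostrin (-3.93), Ndufa4l2 (-3.76) and Hkdc1 (-3.76), and other large rises were in the ascorbate transporter gene Slc23a1 (2.03), Vgf (1.99), Apol6 (1.92) and Egr1 (1.53). In all, 5594 of 13984 genes were called, 2978 higher and 2616 lower, of which 172 rose and 525 fell at least 2-fold. Scaling to column totals lowered the share of calls that were higher from 53.2% to 38.9%. Among 21 endoderm genes tested, 19 fell and 0 rose (19 and 0 adjusted over the list alone), with a median of -2.7 (adjusted p = 0.00056 with an estimated correlation). Glycolysis and hypoxia genes fell in 20 of 22 cases and rose in 0 (the same adjusted over the list alone), with a median of -0.74 (adjusted p = 0.11 with an estimated correlation), among them Egln3 (403 ± 61.7 against 1470 ± 118, -1.87) and Ankrd37 (-2.05). Most of these genes were lower than in WT in the other 2 mutants at day 0 as well. Formative and primed pluripotency genes rose in 8 of 14 cases and fell in 1 (the same adjusted over the list alone), with Sall2 rising from 106 ± 3.6 to 204 ± 19.5 and Otx2 falling (-1.48), and their median was 0.39 (adjusted p = 0.23 with an estimated correlation). For imprinted genes the median was 0.25 and the mean -0.12, with 11 of 23 higher and 5 lower (the same adjusted over the list alone), and the test pointed up (adjusted p = 0.14 with an estimated correlation). H19 fell from 283 ± 17.6 to 38.5 ± 2.84 (-2.85) and Meg3 fell (-3.22).

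The comparison of Mll2-KO with WT at day 0 asked what loss of MLL2, together with 4-OHT, changed in stem cell culture. Lef1 (chromosome 3, 131110471 to 131224356), a transcription factor of the Wnt pathway, fell from 268 ± 42.4 to 13.6 ± 1.3 (-4.19, 18.3-fold lower, adjusted p = 6e-14). Khdc3 (chromosome 9, 73101836 to 73104438), a gene of oocytes and early embryos, fell from 704 ± 25.7 to 70.4 ± 40.5 (-3.54, adjusted p = 1.9e-08), and A2m (chromosome 6, 121635376 to 121679227), a protease inhibitor gene, fell from 441 ± 103 in WT (-5.27, adjusted p = 4.4e-11). The stress factor Ddit3 rose from 257 ± 16.1 to 1310 ± 325 (2.32, adjusted p = 7.3e-12), and Gata2 rose from 28.1 ± 12.8 to 171 ± 65.1 (2.59, adjusted p = 4e-07). Stc1 (chromosome 14, 69029238 to 69041804) had no reads in Mll2-KO against 56.5 ± 13.6 in WT and was at least 22.9-fold lower. Further falls were in Aoc3 (-4.32), Grin1 (-4.19), Adm (-3.82), Ndufa4l2 (-3.53) and Ier3 (-3.34), and further rises in Cox6a2 (3.25), Trim66 (2.77), Spata31d1b (2.40), Apc2 (2.20) and G0s2 (2.09). The call of higher Cers1 (2.61) was lost without the count filter, with DESeq2 and without 1 WT library. Of 13984 genes, 3191 were higher and 3405 lower, and 277 rose and 737 fell at least 2-fold. All 13 of the 2-cell-like genes tested fell (13 adjusted over the list alone), with a median of -2.33 (adjusted p = 0.21 with an estimated correlation), including Zscan4a from 383 ± 69.6 to 57.8 ± 16.7 (-2.73). These are near-identical copies, and the sources used here do not state how reads were shared among them. Germline genes fell in 17 of 22 cases and rose in 0 (the same adjusted over the list alone), with a median of -0.72 (adjusted p = 0.10 with an estimated correlation), and Sycp1 fell from 252 ± 56.5 to 45.9 ± 9.41 (-2.43). Glycolysis and hypoxia genes fell in 20 of 22 cases and rose in 1 (the same adjusted over the list alone), with a median of -0.91 (adjusted p = 0.10 with an estimated correlation). Egln3 fell from 1470 ± 118 to 174 ± 17.4 (-3.07) and Slc2a3 rose (0.25). Genes of the integrated stress response rose in 14 of 15 cases and fell in 1 (the same adjusted over the list alone), with a median of 0.88 (adjusted p = 0.23 with an estimated correlation). Trib3 rose from 1060 ± 47.1 to 3710 ± 663 (1.80). Of 23 naive and core pluripotency genes, 10 rose and 8 fell (the same adjusted over the list alone), with Tbx3 rising from 2430 ± 132 to 6400 ± 997 (1.39), Klf4 rising (0.70) and Tdgf1 falling (-0.80). Their median was -0.04 and their mean 0.09.

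The comparison of the double-KO with WT at day 0 asked what joint loss changed, again with 4-OHT in the mutant only. The imprinted noncoding RNA H19 (chromosome 7, 142575529 to 142578143) fell from 283 ± 17.6 to 7.69 ± 0.759 (-5.04, 32.8-fold lower, adjusted p = 6.4e-15). Klb (chromosome 5, 65348314 to 65384007), a co-receptor gene of FGF signalling, fell from 193 ± 21.2 to 8.05 ± 1.77 (-4.43, adjusted p = 1.7e-12). Slc23a1 (chromosome 18, 35614604 to 35627244) rose from 26.1 ± 1.31 to 182 ± 16.9 (2.75, adjusted p = 4e-11), the cystine transporter gene Slc7a11 rose from 17.9 ± 3.26 to 91.7 ± 11.8 (2.30, adjusted p = 7.3e-07), and Scn3a rose from 52.2 ± 2.23 to 258 ± 17.1 (2.28, adjusted p = 8.1e-11). Adm (-4.95), A2m (-4.69) and Pgbd1 (-4.31) fell, and Htr1b (2.97), Aox3 (2.96), Shank1 (2.7), Inhbe (2.38) and Vgf (2.28) rose. With only 1 to 3 reads in the double-KO, the ratio of means was 190 for Stc1 (interval 33.8 to 7550), 105 for Ppp1r3c (28.9 to 875), 195 for Xlr3a (34.7 to 7750) and 1690 for Eif3j1 (468 to 14000). Xlr3a and Eif3j1 have near-identical copies in the genome, which left their values uncertain. Calls numbered 7513, with 3723 higher and 3790 lower (3017 and 4465 scaled to column totals), and 339 rose and 1374 fell at least 2-fold. Endoderm genes fell in 18 of 21 cases and rose in 0 (the same adjusted over the list alone), with a median of -2.71 (adjusted p = 0.0029 with an estimated correlation), and Dab2 fell from 1530 ± 173 to 78.4 ± 14.7 (-4.28). Germline genes fell in 20 of 22 cases and rose in 1 (the same adjusted over the list alone), with a median of -1.49 (adjusted p = 0.017 with an estimated correlation). Tex11 fell from 364 ± 8.94 to 51.6 ± 7.49 (-2.81) and Sycp1 from 252 ± 56.5 to 24.8 ± 4.73 (-3.28). All 13 of the 2-cell-like genes tested fell (13 adjusted over the list alone), with a median of -3.41 (adjusted p = 0.14 with an estimated correlation), and Zscan4b fell from 393 ± 42.4 to 29.8 ± 12.5 (-3.77). Cholesterol synthesis genes rose in 19 of 24 cases and fell in 1 (the same adjusted over the list alone), with a median of 0.70 (adjusted p = 0.46 with an estimated correlation), and Fdps rose from 1340 ± 27.9 to 3070 ± 191 (1.2). Again, glycolysis and hypoxia genes stood lower than in WT, with 18 of 22 falling and 1 rising (the same adjusted over the list alone) and a median of -0.52 (adjusted p = 0.18 with an estimated correlation).

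Against Mll1-KO, the day 0 double-KO asked what loss of MLL2 with 4-OHT changed in cells already without MLL1. Sycp1 (chromosome 3, 102818499 to 102936100), which encodes a protein of the synaptonemal complex, fell from 198 ± 17.1 to 24.8 ± 4.73 (-2.96, adjusted p = 9e-10). The germ cell factor Sohlh2 fell from 298 ± 24 to 39.4 ± 4.77 (-2.89, adjusted p = 6.5e-11) and the fatty acid binding gene Fabp5 from 203 ± 12.2 to 26.4 ± 6.13 (-2.92, adjusted p = 4.1e-08). Magohb (-2.93), Zscan4b (-2.88) and Zscan4c (-2.75) also fell. Ddit3 rose from 212 ± 16 to 714 ± 57.2 (1.75, adjusted p = 1.1e-09) and G0s2 from 27.7 ± 11.9 to 110 ± 10.9 (2.02, adjusted p = 1.1e-05), as did Pga5 (2.15). Cers1 had no reads in Mll1-KO against 75.8 ± 30.7 in the double-KO and was at least 26.6-fold higher, and it shares its locus with Gdf1, which was lower (-3.18). The ratio for Eif3j1 was 3030 (interval 837 to 25000), and the call of lower Amd1 (-2.80) was lost when any of 3 single libraries was left out. Of 5728 calls, 2645 were higher and 3083 lower, with 235 rises and 785 falls of at least 2-fold. Germline genes fell in 16 of 22 cases and rose in 0 (the same adjusted over the list alone), with a median of -0.91 (adjusted p = 0.041 with an estimated correlation). Among 2-cell-like genes, 13 of 13 fell (13 adjusted over the list alone), with a median of -2.44 (adjusted p = 0.12 with an estimated correlation). Cholesterol synthesis genes rose in 22 of 24 cases and fell in 0 (the same adjusted over the list alone), with a median of 1.01 (adjusted p = 0.31 with an estimated correlation), led by Tm7sf2 (1.53) and Fdps (1.49). Integrated stress response genes rose in 10 of 15 cases and fell in 0 (12 and 0 adjusted over the list alone), with a median of 0.52 (adjusted p = 0.31 with an estimated correlation). For glycolysis and hypoxia genes the median was 0.02, with 5 of 22 higher and 7 lower (5 and 8 adjusted over the list alone).

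Against Mll2-KO, the day 0 double-KO asked what loss of MLL1 changed where both groups had received 4-OHT. Lef1 rose from 13.6 ± 1.3 to 144 ± 24.1 (3.30, adjusted p = 1.9e-12), Lefty2 (chromosome 1, 180893108 to 180899103), an inhibitor of Nodal signalling, rose from 58.1 ± 12 to 296 ± 52.2 (2.33, adjusted p = 3.8e-10), and Myc (chromosome 15, 61985391 to 61990374) rose from 199 ± 36.1 to 962 ± 45.8 (2.28, adjusted p = 4.4e-12). Ina rose from 176 ± 7.26 to 1110 ± 79.6 (2.65). Hkdc1 (chromosome 10, 62383137 to 62422491), a hexokinase-like gene, fell from 120 ± 15.2 to 4.58 ± 2.66 (-4.57, adjusted p = 8.9e-09), H19 fell from 152 ± 12.9 to 7.69 ± 0.759 (-4.14, adjusted p = 2.2e-13) and Srgn fell from 676 ± 53.7 to 44 ± 14.5 (-3.97, adjusted p = 8.8e-13). Klb (-4.87), Bmper (-4.09), Nostrin (-4.05) and Aqp8 (-4.00) fell as well, and Msc (2.46), Egr1 (2.22), Lpar4 (2.11) and Nnat (2.06) rose. The ratios of Eif3j1 and Xlr3a, with uncertain mapping, were 2210 (interval 611 to 18200) and 178 (interval 31.6 to 7060). Calls numbered 6667, with 3266 higher and 3401 lower, of which 324 rose and 779 fell at least 2-fold. The share of calls that were higher dropped from 49% to 38% with scaling to column totals. Endoderm genes fell in 19 of 21 cases and rose in 0 (20 and 0 adjusted over the list alone), with a median of -2.44 (adjusted p = 0.0014 with an estimated correlation), and the receptor gene Cubn fell from 2370 ± 176 to 196 ± 7.69 (-3.58). Glycolysis and hypoxia genes rose in 17 of 22 cases and fell in 2 (the same adjusted over the list alone), with a median of 0.50 (adjusted p = 0.33 with an estimated correlation). Ldha rose from 9500 ± 1620 to 18100 ± 309 (0.95). Formative and primed genes rose in 10 of 14 cases and fell in 2 (11 and 2 adjusted over the list alone), with a median of 0.60 (adjusted p = 0.20 with an estimated correlation). Germline genes fell in 16 of 22 cases and rose in 2 (the same adjusted over the list alone), with a median of -0.77 (adjusted p = 0.20 with an estimated correlation).

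Overlaps at day 0 asked whether losing 1 protein changed the same genes with and without the other. For Mll2 loss, 3856 genes were called in the same direction in both backgrounds, 1797 higher and 2059 lower against 604 and 751 expected by chance, and 101 were called in opposite directions against 1348 expected. Log2 changes of all genes correlated with r = 0.68 in this pair. Of the 1014 genes changed at least 2-fold in Mll2-KO, 682 (67.3%) were called in the same direction between double-KO and Mll1-KO. For Mll1 loss, 3824 genes were shared, 2038 higher and 1786 lower (1427 and 2388 scaled to column totals) against 696 and 636 expected, with 132 in opposite directions and r = 0.666, and 503 of 697 genes changed at least 2-fold (72.2%) recurred. The labels do not say whether the double-KO was made from the Mll1-KO line. If it was, differences of that line other than Mll1 loss would recur in the overlap for Mll1 loss too. Non-additivity, the difference between the effect of Mll2 loss without MLL1 and with it, was called for 1277 genes, 618 higher and 659 lower. Among these, A2m (4.60), Grin1 (4.44), Ndufa4l2 (4.16) and Aoc3 (3.52) were high only in WT, which held 441 ± 103 of A2m, 175 ± 51.9 of Grin1, 494 ± 121 of Ndufa4l2 and 68.5 ± 20.3 of Aoc3. Gata2 (-2.15) and Slc43a3 (-1.78) were below the additive value.

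**Figure D2:**
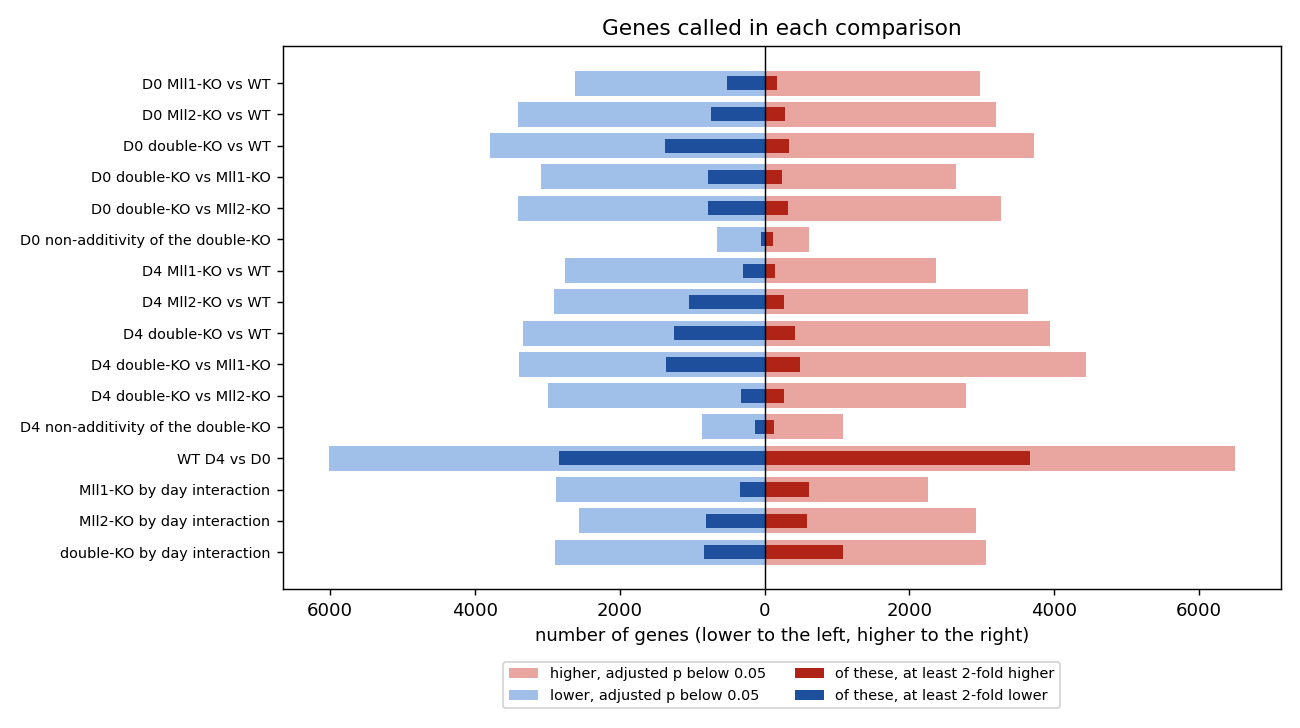
Number of genes called by limma in each comparison, lower to the left and higher to the right. Dark parts of the bars are genes changed at least 2-fold.

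The comparison of Mll1-KO with WT at day 4 asked what loss of MLL1 changed after 4 days of differentiation. H19 fell from 11200 ± 834 to 547 ± 9.19 (-4.35, 20.4-fold lower, adjusted p = 4.2e-27). The endoderm-derived lipoprotein gene Apoa1 (chromosome 9, 46228580 to 46230466) fell from 414 ± 50.2 to 46.5 ± 8.6 (-3.14, adjusted p = 1.8e-14) and the fetal plasma protein gene Afp from 115 ± 5.74 to 15.9 ± 8.17 (-2.87, adjusted p = 3.9e-09). Akr1c18 (chromosome 13, 4132615 to 4150654), a progesterone-converting enzyme gene, rose from 7.02 ± 1.84 to 52.8 ± 7.99 (2.76, adjusted p = 3e-07), and the mesothelial genes Upk3b (chromosome 5, 136038496 to 136046487; 61.4 ± 10.7 to 211 ± 6.8, 1.78, adjusted p = 2.9e-06) and Msln (1.77) rose. Timd2 (-2.96) fell, as did 2 noncoding RNAs of the Dlk1 domain, Rian (28.3 ± 8.39 against 125 ± 23.3, -2.13) and Meg3 (-1.94), and the endoderm gene Amn (-1.92). Zfp433 had no reads in Mll1-KO against 63.7 ± 83.3 in WT, where 1 library held most of the reads, so no bound on its fold is given. Tmem254c (5.56) lost its call with DESeq2. Both have near-identical copies. There were 5120 calls among 14303 genes, 2367 higher and 2753 lower, with 148 rises and 303 falls of at least 2-fold. Scaling to column totals raised the share that was higher from 46.2% to 60.3%. Endoderm genes fell in 22 of 24 cases and rose in 0 (the same adjusted over the list alone), with a median of -0.90 (adjusted p = 0.0038 with an estimated correlation). Naive and core pluripotency genes fell in 20 of 22 cases and rose in 0 (21 and 0 adjusted over the list alone), with a median of -0.79 (adjusted p = 0.17 with an estimated correlation). Pou5f1 fell from 958 ± 130 to 313 ± 50.4 (-1.61). Fibroblast markers rose in 6 of 14 cases and fell in 1 (7 and 1 adjusted over the list alone), with a median of 0.25 (adjusted p = 0.18 with an estimated correlation). Interferon-stimulated genes rose in 11 of 17 cases and fell in 0 (the same adjusted over the list alone), with a median of 0.51 (adjusted p = 0.17 with an estimated correlation), including Ifit3 (25.4 ± 0.892 to 86.8 ± 9.88, 1.73) and Ifit1 (43.8 ± 6.52 to 133 ± 11.1, 1.59). Hox genes split, with 11 of 34 higher and 7 lower (13 and 7 adjusted over the list alone): Hoxc5 rose from 291 ± 14.1 to 629 ± 40.8 (1.11), and Hoxa9 (121 ± 15.3 to 46.5 ± 2.55) and Hoxa10 (-1.62) fell. Their median was 0.10 and their mean -0.05 (adjusted p = 0.64 with an estimated correlation).

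The comparison of Mll2-KO with WT at day 4 asked what loss of MLL2, with earlier 4-OHT, changed after differentiation. Il3ra (chromosome 14, 14346275 to 14356011), a cytokine receptor gene, fell from 202 ± 12.1 to 6.08 ± 2.46 (-4.91, 30.1-fold lower, adjusted p = 9.1e-13). The laminin gene Lama2 (chromosome 10, 26980036 to 27619758) fell from 87 ± 3.96 to 4.15 ± 2.09 (-4.19, adjusted p = 1.9e-11), Igsf10 (chromosome 3, 59316735 to 59344394) from 227 ± 22.6 to 8.53 ± 2.41 (-4.61, adjusted p = 7.7e-13) and the oxidase gene Nox4 from 122 ± 17.5 to 4.3 ± 5.62 (-5.06, adjusted p = 3.8e-10). The ratio for the integrin gene Itga4 (chromosome 2, 79255426 to 79333123) was 63.9 (interval 21.5 to 313). The phospholipase gene Pla2g5 (chromosome 4, 138799244 to 138863482) rose from 5.88 ± 2.83 to 103 ± 8.71 (4.00, adjusted p = 8.2e-11), Timd2 (chromosome 11, 46668960 to 46707061) from 51.3 ± 9.42 to 582 ± 27.5 (3.49, adjusted p = 1.1e-12), Havcr1 from 4.27 ± 1.11 to 58.8 ± 11.1 (3.51, adjusted p = 5.2e-07) and the endothelial cadherin gene Cdh5 from 10.2 ± 5.52 to 86 ± 14.5 (3.07, adjusted p = 1.8e-07). Pramel7 (3.17), Fbp2 (2.72), Aspa (2.30), Tcf23 (2.28) and Six3 (2.24) also rose, and Ccdc125 (-4.21) fell. Calls numbered 6537, with 3634 higher and 2903 lower, yet at 2-fold or more 264 rose and 1040 fell. The share of calls that were higher went from 55.6% to 34.4% with scaling to column totals, 47.4% with edgeR and 48.9% with DESeq2. All 13 of the 2-cell-like genes tested fell (13 adjusted over the list alone), with a median of -3.53 (adjusted p = 0.023 with an estimated correlation), and Zscan4a fell from 326 ± 95.3 to 16.6 ± 5.36 (-4.22). Hox genes fell in 23 of 34 cases and rose in 2 (24 and 2 adjusted over the list alone), with a median of -0.49 (adjusted p = 0.083 with an estimated correlation). Hoxb13 fell from 506 ± 36.9 to 164 ± 19.7 (-1.63) and Hoxc6 fell (-1.42). Endoderm genes rose in 16 of 24 cases and fell in 3 (17 and 3 adjusted over the list alone), with a median of 0.46 (adjusted p = 0.083 with an estimated correlation). Sox17 rose from 420 ± 28.2 to 761 ± 16.9 (0.86) and Sox7 rose (1.09), but Apoa1 fell (-1.02). Naive and core pluripotency genes rose in 13 of 22 cases and fell in 1 (14 and 2 adjusted over the list alone), with a median of 0.38 (adjusted p = 0.34 with an estimated correlation). Pou5f1 rose from 958 ± 130 to 2370 ± 195 (1.31). Germline genes fell in 14 of 22 cases and rose in 3 (15 and 4 adjusted over the list alone), with a median of -0.79 (adjusted p = 0.10 with an estimated correlation). Sycp2 fell from 43.7 ± 9.86 to 4.39 ± 1.95 (-3.11). Retinoic acid response genes fell in 9 of 17 cases and rose in 5 (the same adjusted over the list alone), with a median of -0.18 (adjusted p = 0.083 with an estimated correlation). Stra8 fell from 1800 ± 119 to 938 ± 61.1 (-0.94).

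The comparison of the double-KO with WT at day 4 asked what joint loss changed after differentiation. Rbp4 (chromosome 19, 38116629 to 38125281), the plasma carrier gene of retinol, fell from 2120 ± 236 to 85.2 ± 7.75 (-4.62, 24.6-fold lower, adjusted p = 4.3e-23). Casp8 (chromosome 1, 58795374 to 58847503), the initiator caspase gene of the extrinsic pathway, fell from 77.7 ± 13.5 to 2.02 ± 0.42 (-4.70, adjusted p = 3.6e-11), the lysosomal protease gene Ctsh from 485 ± 53.8 to 18 ± 5.34 (-4.71, adjusted p = 3.5e-17) and Igsf10 from 227 ± 22.6 to 3.53 ± 2.09 (-5.76, adjusted p = 5.5e-15). Xist (chromosome X, 103460366 to 103483254), the noncoding RNA of X inactivation, rose from 19.8 ± 4.68 to 454 ± 59.4 (4.47, 22.1-fold, adjusted p = 2.2e-16). Pla2g5 rose to 214 ± 12 (5.04, adjusted p = 7.3e-13), Wnt6 (chromosome 1, 74771892 to 74785322) from 125 ± 38.6 to 764 ± 75.9 (2.65, adjusted p = 6.3e-14) and the chemokine gene Ppbp from 70.7 ± 17.2 to 482 ± 23.1 (2.78, adjusted p = 7.8e-12). Slfn2 (3.32), Aox4 (2.95), Mpeg1 (2.93) and Iqcg (2.81) rose, and Il3ra (-5.33), Nrn1 (-4.82), H2-M3 (-4.80) and Ccdc125 (-4.57) fell. For genes with 1 to 3 reads in the double-KO the ratios were 159 for Itga4 (interval 28.2 to 6320) and 140 for Cldn34c1 (24.7 to 5540). There were 7277 calls, 3945 higher and 3332 lower, and 422 rose and 1255 fell at least 2-fold. The share that was higher went from 54.2% to 41.3% with scaling to column totals, 49.6% with edgeR and 48.7% with DESeq2. All 13 of the 2-cell-like genes tested fell (13 adjusted over the list alone), with a median of -3.25 (adjusted p = 0.055 with an estimated correlation). Hox genes fell in 20 of 34 cases and rose in 5 (the same adjusted over the list alone), with a median of -0.52 (adjusted p = 0.12 with an estimated correlation). Hoxa9 fell from 121 ± 15.3 to 9.36 ± 3.78 (-3.61) and Hoxc6 fell (-2.29), while Hoxc5 rose (1.06). Mesoderm genes fell in 11 of 15 cases and rose in 1 (the same adjusted over the list alone), with a median of -0.86 (adjusted p = 0.072 with an estimated correlation). Targets of p53 rose in 18 of 20 cases and fell in 1 (the same adjusted over the list alone), with a median of 0.39 (adjusted p = 0.12 with an estimated correlation). Cdkn1a rose from 2860 ± 211 to 6150 ± 72.3 (1.11). Endoderm genes fell in 16 of 24 cases and rose in 3 (17 and 3 adjusted over the list alone), with a median of -0.29 (adjusted p = 0.15 with an estimated correlation). Among imprinted genes 9 of 25 rose and 12 fell (the same adjusted over the list alone), with H19 falling from 11200 ± 834 to 719 ± 43 (-3.96).

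Against Mll1-KO, the day 4 double-KO asked what Mll2 loss with 4-OHT changed in differentiating cells without MLL1. Smarca1 (chromosome X, 47809368 to 47892974), a chromatin remodeller gene, fell from 532 ± 33.2 to 22.9 ± 5.63 (-4.50, adjusted p = 1.3e-18), the homeobox gene Zfhx4 from 352 ± 23.9 to 17.6 ± 9.58 (-4.37, adjusted p = 1.1e-14) and the protease gene Ctso from 181 ± 12.5 to 6.05 ± 1.26 (-4.70, adjusted p = 2.6e-14). Timd2 rose from 6.12 ± 3.3 to 211 ± 11.6 (4.99, adjusted p = 5.5e-16), the X-linked homeobox gene Rhox5 from 153 ± 15.2 to 1200 ± 99.2 (2.96, adjusted p = 2.6e-20) and Xist from 53.1 ± 8.87 to 454 ± 59.4 (3.08, adjusted p = 2.6e-13). Pla2g5 (4.96), Mpeg1 (3.43), Pnma5 (3.13) and Drp2 (2.83) rose, and Igsf10 (-6.00), H2-M3 (-5.64), Il3ra (-5.17), Susd5 (-4.57) and Casp8 (-4.48) fell. The ratio for Itga4 was 203 (interval 36 to 8050), and Zfp433, with uncertain mapping, was at least 19.8-fold higher. Of 7834 calls, 4443 were higher and 3391 lower, and 495 rose and 1362 fell at least 2-fold. Column totals turned the share of calls that were higher from 56.7% to 36% and moved the median of all genes by -0.108. Hox genes fell in 24 of 34 cases and rose in 2 (24 and 3 adjusted over the list alone), with a median of -0.63 (adjusted p = 0.079 with an estimated correlation). Of 13 2-cell-like genes, 12 fell (12 adjusted over the list alone), with a median of -2.16 (adjusted p = 0.079 with an estimated correlation). Endoderm genes rose in 20 of 24 cases and fell in 1 (22 and 1 adjusted over the list alone), with a median of 0.53 (adjusted p = 0.079 with an estimated correlation), led by Sox7 (1.94) and Srgn (1.32). Naive and core pluripotency genes rose in 17 of 22 cases and fell in 1 (18 and 1 adjusted over the list alone), with a median of 0.70 (adjusted p = 0.35 with an estimated correlation). Dnmt3a fell (-1.03) and Dnmt3l rose (1.33).

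Against Mll2-KO, the day 4 double-KO asked what Mll1 loss changed where both groups had received 4-OHT. H19 fell from 8550 ± 482 to 719 ± 43 (-3.57, adjusted p = 5e-25), Rbp4 from 333 ± 29 to 85.2 ± 7.75 (-1.95, adjusted p = 7.6e-15), Afp from 69.3 ± 8.01 to 16.6 ± 4.05 (-2.01, adjusted p = 8.7e-07) and Hoxa10 from 98 ± 14.9 to 27 ± 6.3 (-1.83, adjusted p = 8e-07). In the Dlk1 domain Meg3 fell from 112 ± 24.2 to 26.7 ± 4.97 (-2.02, adjusted p = 7.8e-07) and Rian fell (-1.83). Xist rose from 67.2 ± 0.805 to 454 ± 59.4 (2.73, adjusted p = 7.2e-12), the activin subunit gene Inhba from 14.7 ± 2.27 to 69.3 ± 14.4 (2.15, adjusted p = 5.3e-08) and Msln from 22.8 ± 6.58 to 92.6 ± 15.1 (2.00, adjusted p = 4.4e-06). Dkk2 (2.49), Upk3b (2.27), Entpd3 (2.13), Tmprss11f (2.08) and Ppbp (1.96) rose, and Havcr1 (-2.30) fell. Tmem254c (6.20) and Tmem254b (-3.96), near-identical copies, each lost their calls with DESeq2, and Amd1 had a ratio of 71.5 (interval 24.1 to 350). Of 5770 calls 2780 were higher and 2990 lower (3177 and 2561 scaled to column totals), with 269 rises and 329 falls of at least 2-fold. Endoderm genes fell in 22 of 24 cases and rose in 1 (the same adjusted over the list alone), with a median of -0.72 (adjusted p = 0.014 with an estimated correlation), where Amn fell (-1.65) and Thbd rose (1.32). Fibroblast markers rose in 11 of 14 cases and fell in 0 (the same adjusted over the list alone), with a median of 0.85 (adjusted p = 0.07 with an estimated correlation). Naive and core pluripotency genes fell in 16 of 22 cases and rose in 2 (the same adjusted over the list alone), with a median of -0.66 (adjusted p = 0.22 with an estimated correlation). Pou5f1 fell from 2370 ± 195 to 939 ± 18.2 (-1.33). Interferon-stimulated genes rose in 13 of 17 cases and fell in 1 (14 and 1 adjusted over the list alone), with a median of 0.58 (adjusted p = 0.18 with an estimated correlation). In Mll2-KO against WT, which shares the Mll2-KO libraries with this comparison, 10 of the 17 fell and 2 rose (the same adjusted over the list alone), with a median of -0.56 (adjusted p = 0.19 with an estimated correlation). Of 34 Hox genes 9 rose and 13 fell (11 and 13 adjusted over the list alone), with a median of 0.05 and a mean of -0.17, as Hoxc5 rose (1.36) and Hoxa9 fell (-2.27).

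Overlaps at day 4 asked whether losing 1 protein changed the same genes with and without the other. For Mll2 loss 4816 genes were called in the same direction in both backgrounds, 2563 higher and 2253 lower against 1129 and 688 expected, with 120 in opposite directions and r = 0.822. Scaled to column totals the shared genes were 1346 higher and 2985 lower, and for Mll1 loss 1786 higher and 1195 lower. The genes shared for Mll2 loss were 2078 higher and 2479 lower with edgeR, and 1887 and 2217 with DESeq2. Of 1304 genes changed at least 2-fold in Mll2-KO, 1153 (88.4%) were called in the same direction between double-KO and Mll1-KO. For Mll1 loss 2927 genes were shared, 1382 higher and 1545 lower against 460 and 576 expected, with 172 in opposite directions and r = 0.485, and 253 of 451 genes changed at least 2-fold (56.1%) recurred. As at day 0, differences of the Mll1-KO line other than Mll1 loss could recur in this overlap, if the double-KO was made from that line. Non-additivity was called for 1951 genes, 1085 higher and 866 lower. That count went to 1000 with other libraries in the fit and to 1269 without 1 Mll2-KO library. Entpd3 (2.82) was above the additive value, and Mef2c (-2.37), Gbp7 (-2.32) and Bicd1 (-2.07) below it.

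**Figure D3:**
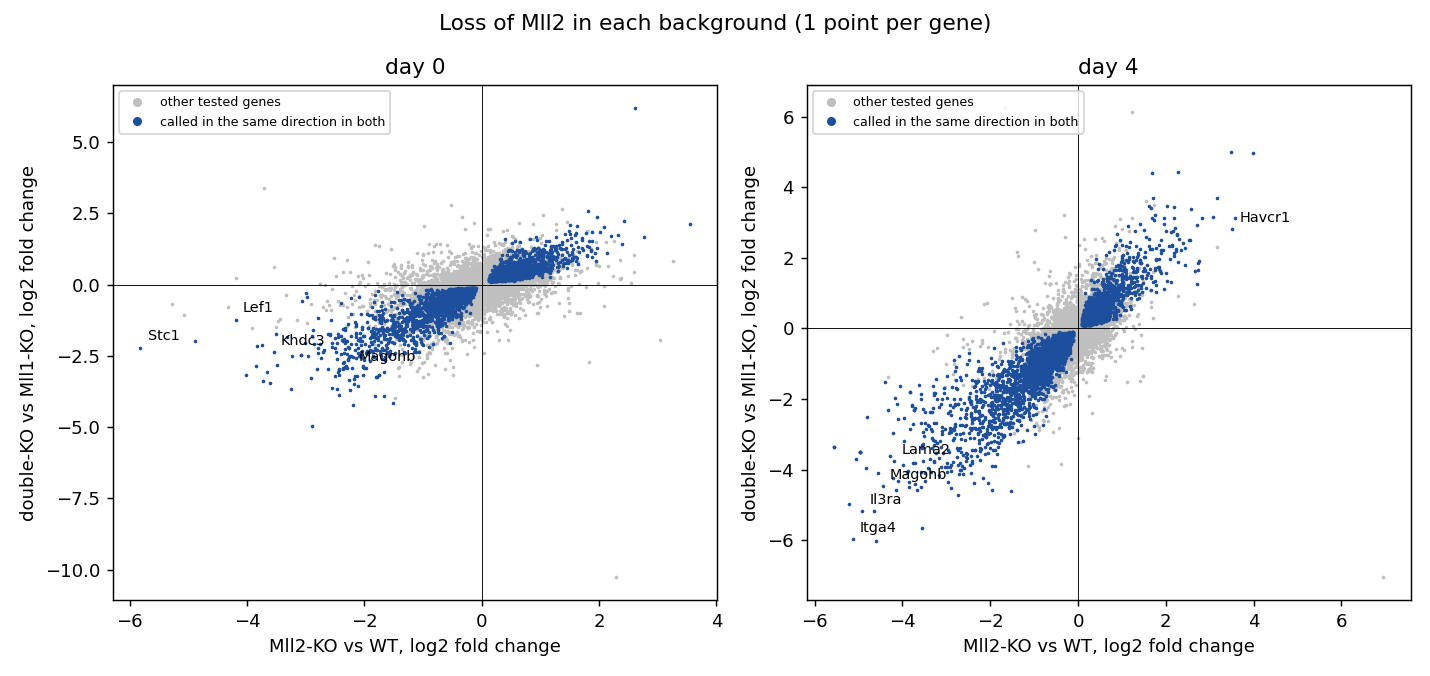
Log2 fold change of each gene on loss of Mll2, with MLL1 present (Mll2-KO against WT, horizontal) and absent (double-KO against Mll1-KO, vertical), at day 0 and day 4. Blue points are genes called in the same direction in both.

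WT cells at day 4 against day 0 gave the course of differentiation itself. The retinoic acid targets Cyp26a1 (21.7 ± 3.52 to 9970 ± 317, 8.79) and Rarb (5.37 ± 0.734 to 2620 ± 62, 8.69) rose, as did the matrix genes Col12a1 (chromosome 9, 79598991 to 79718831; 2.3 ± 0.026 to 3270 ± 386, 9.94, adjusted p = 2.8e-24) and Ecm1 (chromosome 3, 95734147 to 95739569; 29.7 ± 1.94 to 18100 ± 962, 9.20, adjusted p = 3e-27). The pluripotency gene Tdgf1 fell from 33400 ± 694 to 140 ± 30.9 (-7.91, adjusted p = 5.2e-29) and Olig1 (chromosome 16, 91269772 to 91271933) from 1210 ± 49.3 to 10.4 ± 4.57 (-6.83, adjusted p = 5.7e-19). Nphs1 (-7.67), Khdc3 (-7.25) and Tcl1 (-6.68) fell, and Masp1 (8.96) rose. For genes without reads at day 0 the rises were at least 344-fold for Ccdc80, 322-fold for Svep1, 316-fold for Hoxc8 and 242-fold for Pcdh7, and with 1 to 3 reads the ratio was 9890 for Col3a1 (interval 2740 to 81700). Of 15114 genes 12522 were called, 6499 higher and 6023 lower, with 3669 rises and 2846 falls of at least 2-fold. Quantile scaling moved the median of all genes by -0.183 and turned the calls to 5852 higher and 6800 lower. Column totals moved the median by 0.122 and gave 7071 higher and 5454 lower. All 34 Hox genes tested rose (34 adjusted over the list alone), with a median of 5.33 (adjusted p = 0.0004 with an estimated correlation). Retinoic acid response genes rose in 15 of 17 cases and fell in 1 (the same adjusted over the list alone), with a median of 4.62 (adjusted p = 0.0004 with an estimated correlation). Endoderm genes rose in 23 of 24 cases and fell in 1 (the same adjusted over the list alone), with a median of 2.17 (adjusted p = 0.00077 with an estimated correlation). Imprinted genes rose in 22 of 25 cases and fell in 2 (the same adjusted over the list alone), with a median of 2.65 (adjusted p = 0.0004 with an estimated correlation). Igf2 rose from 168 ± 20.8 to 23800 ± 894 (7.15). Naive and core pluripotency genes fell in 23 of 23 cases (23 adjusted over the list alone), with a median of -4.39 (adjusted p = 0.06 with an estimated correlation), and glycolysis and hypoxia genes in 22 of 22 (22 adjusted over the list alone), with a median of -1.66 (adjusted p = 0.06 with an estimated correlation).

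Interactions asked whether the effect of a genotype differed between days, a positive value meaning that the change against WT was more positive at day 4 than at day 0. For Mll1-KO 5136 genes were called, 2260 higher and 2876 lower, and column totals turned the share that was higher from 44% to 64.7% and moved the median of all genes by 0.113. Endoderm genes differed upward in 16 of 24 cases and downward in 4 (17 and 4 adjusted over the list alone), with a median of 1.69 (adjusted p = 0.00028 with an estimated correlation), the fall being deeper at day 0. Large differences of single genes were Bmper (3.73) and A2m (3.85) upward, and Apoa1 (-3.28), Ttn (-3.02), Apob (-2.93) and Slc23a1 (-2.84) downward. For Mll2-KO 5491 genes were called, 2922 higher and 2569 lower, with 53.2% higher falling to 37.5% under column totals. Lef1 (4.60, adjusted p = 1.6e-15), A2m (5.67), Aoc3 (4.86) and Ndufa4l2 (4.14) were upward, and Il3ra (-4.53, adjusted p = 8e-10), Syt1 (-4.12), Lama2 (-3.91) and Kcnt2 (-3.87) downward. Hox genes differed downward in 15 of 34 cases and upward in 0 (the same adjusted over the list alone), with a median of -1.14 (adjusted p = 0.027 with an estimated correlation). Only 12 of these Hox genes passed the count filter at day 0, so for the others the day 0 effect was a difference between values near 0. Glycolysis and hypoxia genes differed upward in 20 of 22 cases and downward in 0 (the same adjusted over the list alone), with a median of 1.15 (adjusted p = 0.0084 with an estimated correlation). In Mll2-KO against WT at day 4 alone, glycolysis and hypoxia genes rose in 16 of 21 cases and fell in 2 (the same adjusted over the list alone), with a median of 0.31 (adjusted p = 0.14 with an estimated correlation). For the double-KO 5960 genes were called, 3063 higher and 2897 lower, with Timd2 (5.89, adjusted p = 1.3e-10) and A2m (6.39) upward and Smarca1 (-4.24, adjusted p = 1.4e-14), Msrb2 (-4.20) and Syt1 (-4.15) downward. Endoderm genes differed upward in 18 of 24 cases and downward in 1 (the same adjusted over the list alone), with a median of 1.78 (adjusted p = 4.3e-05 with an estimated correlation).

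Overlaps between days asked whether a genotype changed the same genes before and after differentiation. Mll1-KO shared 1267 genes in the same direction, 512 higher and 755 lower against 477 and 505 expected, while 1001 were in opposite directions against 996 expected, with r = 0.194. Mll2-KO shared 2289 genes, 1320 higher and 969 lower against 831 and 609 expected, with 919 in opposite directions and r = 0.377. The double-KO shared 3012 genes, 1521 higher and 1491 lower against 1022 and 787 expected, with 1034 in opposite directions and r = 0.425. With column totals the shared genes of Mll2-KO were 782 higher and 1248 lower, and those of the double-KO 931 higher and 1918 lower. Of genes changed at least 2-fold at day 0 and tested on both days, 37.6% of 596 recurred in Mll1-KO, 53.8% of 820 in Mll2-KO and 59.3% of 1427 in the double-KO.

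**Figure D4:**
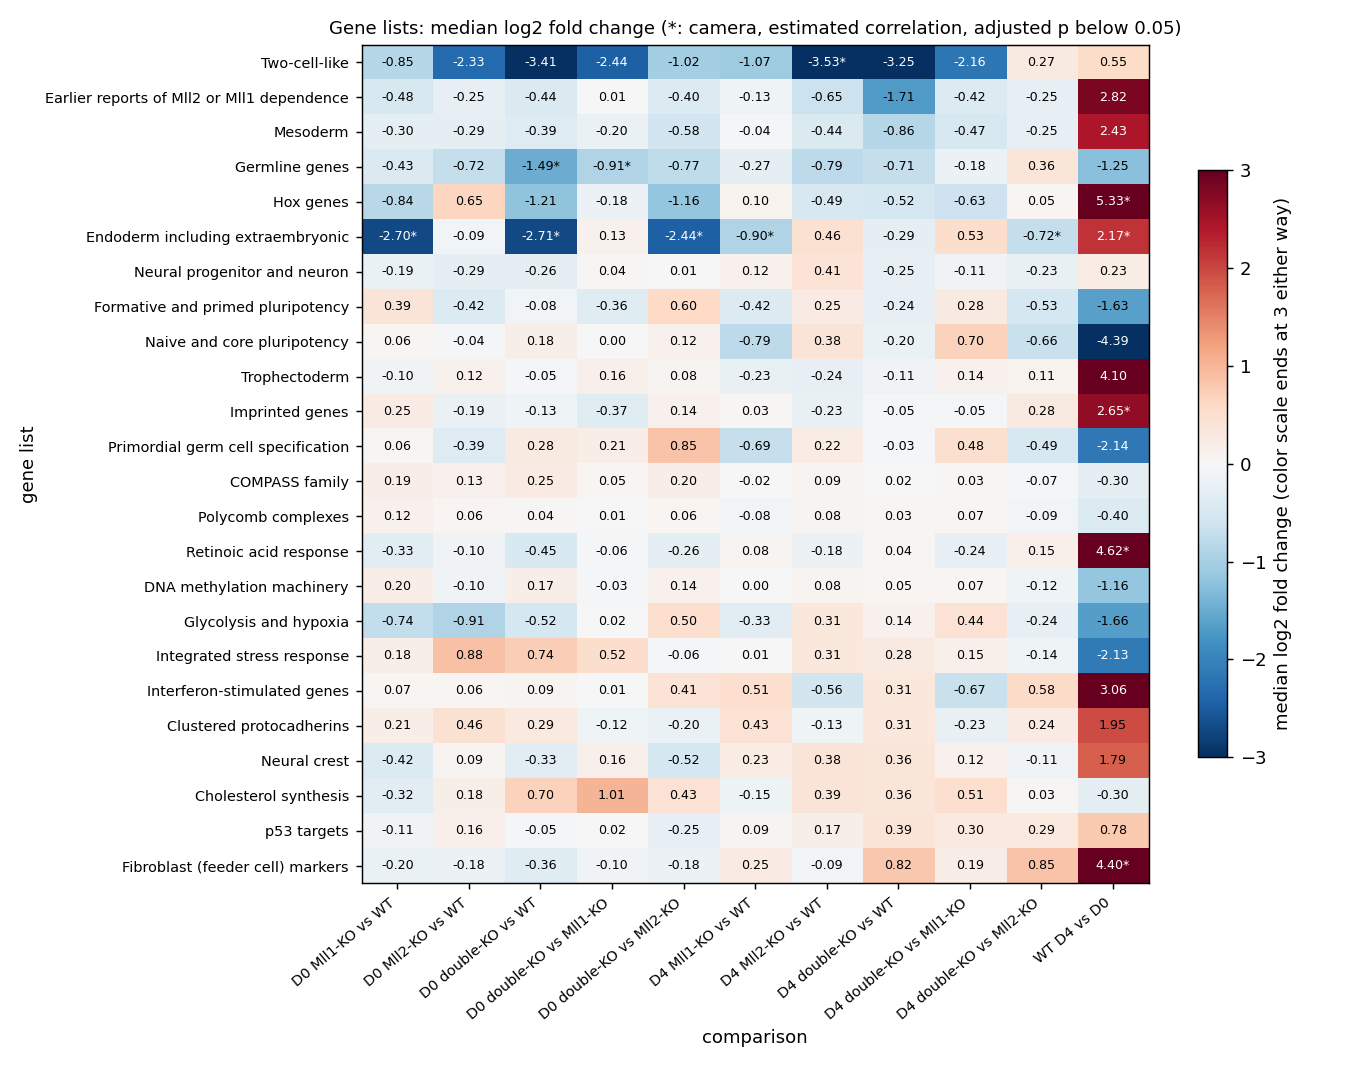
Median log2 fold change of each gene list in each comparison, on a colour scale from -3 to 3. An asterisk marks an adjusted p below 0.05 with an estimated correlation.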

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

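Tests of glycolysis and endoderm explanations, and those of 4-OHT and of the day 4 part of the fall after Mll2 loss, were chosen after the result was seen. Tests of chromosome copies, counting noise and random splits were set beforehand.

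The values in this paragraph stood out because the effect of 1 genotype differed between backgrounds or between days in a direct test of the difference. Non-additivity was called for 1277 genes at day 0 and 1951 at day 4 (1000 with other libraries in the fit and 1269 without 1 Mll2-KO library), and interactions with day for 5136 genes in Mll1-KO, 5491 in Mll2-KO and 5960 in the double-KO. At day 0 non-additivity was largest upward for A2m (4.60), Grin1 (4.44), Ndufa4l2 (4.16), Stc1 (3.61) and Aoc3 (3.52), all high only in WT, and largest downward for Eif3j1 (-12.54), Cox6a2 (-2.42), Gata2 (-2.15), Slc43a3 (-1.78) and Ndufs5-ps (-1.76). At day 4 it was largest upward for Zfp433 (4.92), Entpd3 (2.82), Tmprss11f (2.25), Usp17le (2.19) and Muc13 (2.16), and downward for Susd5 (-2.61), Mef2c (-2.37), Gbp7 (-2.32), H2-M3 (-2.10) and Bicd1 (-2.07). In the Mll1-KO interaction the values were Tmem254c (6.56), Cers1 (4.76), Stc1 (4.35), A2m (3.85), Bmper (3.73), Apoa1 (-3.28), Ttn (-3.02), Apob (-2.93), Afp (-2.87) and Slc23a1 (-2.84). In the Mll2-KO interaction they were Stc1 (6.5), A2m (5.67), Aoc3 (4.86), Lef1 (4.60), Ndufa4l2 (4.14), Itga4 (-5.42), Il3ra (-4.53), Syt1 (-4.12), Lama2 (-3.91) and Kcnt2 (-3.87). For the double-KO they were Eif3j1 (7.10), A2m (6.39), Tmem254c (6.13), Timd2 (5.89), Stc1 (5.83), Tmem254b (-8.08), Itga4 (-5.66), Smarca1 (-4.24), Msrb2 (-4.20) and Syt1 (-4.15). Fitted values of genes with almost no reads in a group, among them Eif3j1, Stc1, Zfp433, Cers1, Itga4, Tmem254b and Tmem254c, depended on the pseudocount. Calls for Stc1 (day 0), Cox6a2, H2-M3, Ndufs5-ps, Zfp433, Muc13, Tmem254c, Tmem254b, Afp and Eif3j1 (by day) were lost under at least 1 alternative.

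Of 22 glycolysis and hypoxia genes, 20 fell at day 0 in Mll1-KO, 20 in Mll2-KO and 18 in the double-KO against WT. The list tests passed at the preset correlation (camera adjusted p = 2.3e-15, 1.6e-18 and 5.3e-10). They did not hold with an estimated correlation (adjusted p = 0.11, 0.10 and 0.18). A single aberrant WT library was excluded, because the lowest WT library lay 0.62 above the highest mutant library in the mean score of the list. Treatment with 4-OHT was excluded as the whole cause, since the untreated Mll1-KO had a median of -0.74. The non-additivity of the list had a median of 0.85, with all 22 genes above 0, which would be consistent with a difference of the day 0 WT cultures at harvest or with a shared effect of both genotypes. These cannot be told apart, because each day holds a single set of WT cultures. A difference of the WT cultures alone would, however, leave the mutants alike. The mean score of the list was -0.547 to -0.389 in the Mll2-KO libraries and -0.172 to -0.052 in those of Mll1-KO and double-KO. These scores argue against the WT cultures as the whole cause.

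Endoderm genes were lower at day 0 wherever Mll1 was lost, and fewer endoderm-like cells in the cultures may account for it as a hypothesis only. The most abundant genes of the list went from WT to Mll1-KO as Lamc1 from 11300 ± 409 to 8970 ± 431, Sparc from 9360 ± 267 to 2800 ± 57.9 and Col4a1 from 8390 ± 136 to 1090 ± 114. A second list of 30 endoderm genes, of which 29 had a mean of at least 10 in WT and 2 were held by another list, had a median of -0.71 in Mll1-KO (18 lower, and Apob at 1.19, Apoe at 0.35 and Grb10 at 0.25 higher) and -0.61 between double-KO and Mll2-KO (21 lower and 1 higher), so fewer cells and lower expression per cell cannot be told apart without single-cell data. In Mll1-KO against WT 5 other lineage lists fell less, with medians from -0.42 (neural crest) to -0.10 (trophectoderm). A loss of differentiated cells of every kind was not excluded by this. Only 15 of 27 neural and 9 of 15 fibroblast genes passed the count filter, and cells of those lineages may be rare in WT culture. The median of -2.44 between double-KO and Mll2-KO leaves a property of the Mll1-KO line possible, since the labels do not say from which line the double-KO was made.

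Falls of at least 2-fold outnumbered rises after Mll2 loss. Loss of a whole chromosome copy in all cells was excluded, with a largest absolute chromosome median of 0.148. This was the X chromosome in Mll2-KO against WT at day 0 (-0.148, with 58 falls and 2 rises of at least 2-fold). In double-KO against Mll1-KO at day 0 X had a median of -0.112, with 67 falls and 3 rises. X held 8.1% and 8.7% of all such falls, with 3.6% of the genes. Loss of part of a chromosome, or of a copy in some of the cells, could not be excluded by these medians. Among genes with a mean of at least 200 the ratio of falls to rises at day 0 was 0.97 in Mll2-KO against WT but 1.73 in double-KO against Mll1-KO. Counting noise of low genes therefore stays open for day 0. At day 4 the ratio among these genes was 2.26 or more, so their excess of falls did not come from low counts. They held only 127 of 1040 falls in Mll2-KO against WT and 199 of 1362 in double-KO against Mll1-KO. For the lower genes counting noise stays open at day 4 as well. The untreated Mll1-KO had ratios of 3.05 at day 0 and 2.05 at day 4, so an excess of falls also arose without the drug and without Mll2 loss. For the falls after Mll2 loss, 4-OHT and the deletion cannot be told apart, because every Mll2-deleted group and no other had received the drug.

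Libraries were regrouped at random between the groups compared. In each comparison of 3 against 3 libraries the real split was 1 of 10, and the highest other split gave 2 calls or fewer, but 10 splits are too few for a share under 0.05. For interactions the real split was 1 of 100, with highest others of 3260 in Mll1-KO, 4130 in Mll2-KO and 5106 in the double-KO, all from splits that kept or exchanged 1 pair of groups whole, whereas splits mixing both pairs gave at most 1 call. For overlaps it was also 1 of 100, with highest others of 1034 or fewer. That ranking could not test chance, because a pair with mixed labels had almost no calls left to overlap. The highest others of 101, 120, 1001 and 1034 equal the numbers called in opposite directions, as when 1 real pair is exchanged whole. For non-additivity, counts as large came in 6 of 100 splits at each day, the real one included. The 5 others gave up to 2772 calls at day 0 and 8808 at day 4. All 5 kept or exchanged 1 pair of groups whole, so they still held real differences between groups. Splits mixing both pairs gave 0 calls. The rank of 6 in 100 therefore could not measure chance, and it neither excluded chance nor spoke for it.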

How the results depend on the processing

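Refits that left the day 0 WT libraries out were chosen after the data were seen, and the other alternatives were set before. Of 442 refits of 23 counts, 440 stayed within the set limits and 2 moved. These limits compared total calls only, so a turn in the balance of rises and falls was not labelled. For Mll2-KO against WT at day 4 the balance turned from 3634 higher and 2903 lower to 3034 and 3372 with edgeR. With DESeq2 it was 2771 higher and 2892 lower. Non-additivity at day 4 moved from 1951 calls to 1000 (565 higher and 435 lower) with other libraries in the fit, and to 1269 without replicate 2 of the day 4 Mll2-KO, and the cause was not tested. Leaving out single libraries gave 1269 to 2092 calls for it. With a replicate block in place of no pairing, day 0 non-additivity gave 1497 calls (713 higher and 784 lower) and day 4 non-additivity 1800. Among 18209 refits of 1114 gene results, 17515 were the same, 687 weaker, 7 stronger and 0 reversed, and among 4257 refits of 264 list results, 4107 were the same, 90 weaker, 60 stronger and 0 reversed, where reversed means that a called result changed sign. A list that was not called counts as the same when its median changes sign. Depth limits what can be said of genes with few reads: at day 4, with 10.7 to 17.1 M reads, a gene that reached 10 normalized counts in fewer than 3 libraries was not tested, and folds against a group without reads are lower bounds.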

Other observations

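Tests of X-linked genes and of neighbouring genes were set before the result was seen. Among fibroblast markers, used as a sign of feeder or stromal cells, Col6a1 rose between Mll2-KO and double-KO at day 4 from 214 ± 18.6 to 574 ± 19 (1.42). Between double-KO and WT at day 4, 9 of 14 rose and 4 fell (9 and 4 adjusted over the list alone), with a median of 0.82 (adjusted p = 0.28 with an estimated correlation). In WT they rose with differentiation in 13 of 14 cases and fell in 1, with a median of 4.40 (adjusted p = 0.0014 with an estimated correlation). Trophectoderm genes rose in WT in 9 of 12 cases and fell in 3, with a median of 4.10 (adjusted p = 0.069 with an estimated correlation), and Krt18 rose from 225 ± 28.1 to 14200 ± 171 (5.98). At day 4 Krt7 fell from 1210 ± 30 in WT to 478 ± 29.3 in Mll2-KO (-1.34) and stood at 1130 ± 28.7 in the double-KO. Clustered protocadherins, which are similar copies with uncertain mapping, rose in WT in 26 of 32 cases and fell in 3, with a median of 1.95 (adjusted p = 0.089 with an estimated correlation). Primordial germ cell genes fell in WT in 10 of 11 cases and rose in 1, with a median of -2.14 (adjusted p = 0.13 with an estimated correlation), and Prdm14 fell from 422 ± 5.93 to 15.7 ± 5.66 (-4.73). In WT the counts of all lists in this part were the same adjusted over the list alone.

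Regulators of DNA methylation changed with differentiation, with 9 of 14 falling and 4 rising in WT and a median of -1.16 (adjusted p = 0.089 with an estimated correlation). Dnmt3l fell from 7180 ± 467 to 357 ± 47 (-4.33) and Tet3 rose from 131 ± 12.5 to 941 ± 12.5 (2.84). Polycomb genes fell in 16 of 27 cases and rose in 9, with a median of -0.40 (adjusted p = 0.13 with an estimated correlation): Phc1 fell from 9970 ± 373 to 993 ± 81.1 (-3.33). COMPASS family genes fell in 11 of 20 cases and rose in 7, with a median of -0.30 (adjusted p = 0.36 with an estimated correlation). In Mll1-KO against WT at day 0, 11 of 20 COMPASS family genes rose and 1 fell (12 and 1 adjusted over the list alone). Their median was 0.19 (adjusted p = 0.17 with an estimated correlation), and Setd1b rose from 541 ± 44.3 to 1310 ± 69.9 (1.28). Mesoderm genes rose in WT in 10 of 17 cases and fell in 5 (median 2.43, adjusted p = 0.25 with an estimated correlation), neural crest genes rose in 7 of 11 and fell in 3 (median 1.79, adjusted p = 0.18 with an estimated correlation), and neural genes rose in 8 of 19 and fell in 8, with a median of 0.23 that turned to -0.10 under quantile scaling. Genes reported earlier to depend on MLL2 or MLL1 fell in 5 of 7 cases and rose in 1 in the day 4 double-KO (5 and 1 adjusted over the list alone), with a median of -1.71 (adjusted p = 0.12 with an estimated correlation). Cholesterol synthesis genes fell in 14 of 24 cases and rose in 1 in WT (median -0.30, adjusted p = 0.66 with an estimated correlation). For 13 mitochondrially encoded genes 0 were in the table, and of 8 Y chromosome genes 3 were in the table and 0 were tested.

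Xist stood at 386 to 494 in the 3 day 4 double-KO libraries and at 15 to 24.4 in WT. In that comparison the median of 506 X-linked genes was -0.059, where 95% of 2000 random sets of autosomal genes had medians between -0.002 and 0.059, and the X-linked minus autosomal difference was -0.087. X inactivation in part of the cells might lower X-linked genes so. But the X-linked median was lower still at day 0 in Mll2-KO against WT (-0.148), where Xist stood at 1.53 to 8.06 against 0 to 7.66. It was also lower at day 0 in double-KO against Mll1-KO (-0.112), where Xist was not called higher. There Xist stood at 27.6 to 37 against 13.4 to 23.6, without overlap, so a smaller rise is not ruled out. Where Xist rose in double-KO against Mll1-KO at day 4 (3.08), the X-linked median was 0.01 beside 0.044 for all genes. The shift therefore cannot be told apart from other changes of X-linked genes without data on single cells.

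Of the genes at least 2-fold lower after Mll2 loss in both backgrounds at day 4, 839 had a position. Among these, 156 (18.6%) had an adjacent tested gene in the set whose symbol began with other letters. In 2000 random draws the median was 89 (10.6%), the 95th percentile 109 and the highest 132. Gene families were judged by the first letters of the symbol alone. Related genes with unlike symbols, overlapping transcripts and co-expressed domains were not excluded as a source of the excess, and no test of a mechanism was made.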
